A study of Caenorhabditis elegans with 11 samples.

How the data were processed

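Gene expression was measured in whole wild-type N2 Caenorhabditis elegans, the standard laboratory strain of this nematode. Per the labels' protocols, populations were synchronised by bleaching gravid adults, and the L1 larvae received 25 uM of a betalain in liquid S medium 16 to 18 h after hatching, for 48 h at 20 °C. The animals are described in the labels as young adults of 3 days after hatching. Betalains are plant pigments made of betalamic acid joined to an amine. The compounds were indicaxanthin, which is the proline-betaxanthin, phenylalanine-betaxanthin, and indoline carboxylic acid-betacyanin. Total RNA was extracted with TRIzol and cleaned on PureLink columns, 3.5 ng per sample was copied into cDNA with the GeneChip WT Pico kit, and biotin-labelled cDNA was hybridised to Affymetrix arrays, per the labels' protocols and the series' design text. Groups and trial numbers came from the labels, which gave 2 control arrays and 3 arrays for each betalain, each called an independent trial. What was shared within a trial is not given in the sources used here, so the p-values measure the spread between these samples.

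The authors' deposited matrix holds 1 log2 value per transcript cluster and array, for 29317 clusters on 11 arrays. The values were made with RMA, per the submitters' processing notes, which is background correction, quantile normalization and summarising of probes. The RMA version, the array model, the annotation release and the software of the comparison tables are not given in the sources used here. The authors' deposited tables compare each betalain with control and give, per the file headers, an unadjusted p-value, a linear ratio of treated over control, and an F score with its sums of squares. The table for indicaxanthin lists only clusters with a p-value under 0.05, while the other tables list all clusters. Those tables also pair clusters with gene names and were used for naming. No table gave values per array.

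Of the 29317 clusters, 27055 carried a gene name and 26811 of these matched the reference gene table (NCBI RefSeq locus tags, accessions and symbols), which supplied current symbols and biotypes. The 2262 clusters without a name were left out of the tests. For 189 clusters the visible assignment named more than 1 gene, and the single name in the gene-name column was used. Probes can be shared within multi-copy families such as histones, vitellogenins, major sperm proteins and hsp-16, so single members of these families are uncertain. Coordinates were not used here, since the genome build of the annotation is not given in the sources used here.

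Each comparison was fitted with limma (lmFit and eBayes, defaults) on the log2 values, with all 11 arrays in 1 model, no block, and p-values adjusted by the Benjamini-Hochberg method at 0.05. Clusters with a mean over all arrays above the 25th percentile of named clusters, a log2 level of 1.523, were tested, which left 20291. The model had 7 residual degrees of freedom and a prior of 1.93. Standard errors (SE) and adjusted p-values of genes below are limma's. There were 7 comparisons: each betalain against control, the mean of the 3 betalains against control, and each pair of betalains. No array signal has a counting error, so the number of arrays limits the precision.

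Gene lists, 29 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 cluster per gene (the one of highest mean; 20054 genes), adjusted over the lists of a comparison. They cover stress responses, insulin signalling and DAF-16 targets, detoxification, metabolism, immunity, germ line and embryo, cuticle and moulting, basic cell machinery, and tissues. Camera with an estimated correlation and limma's fry were run beside it. Fry tests whether the members of a list move one way on balance, or in its mixed form in either direction, and does not compare a list with other genes. Within each list the limma p-values were also adjusted over the list alone. The lists, the tests, the filter, the alternatives named next and the rule for naming genes were chosen before the data were examined.

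The naming rule took, for each betalain against control, up to 10 genes higher and 10 lower with the largest change among those past the threshold whose treated arrays did not overlap the control arrays, and 5 each for the mean of the betalains and for pairs. Where too few passed, 5 per direction with the smallest p-values were given as values. It added up to 4 members with the smallest p-values from each list described, and 13 stress and ageing genes in every comparison with control. The same rule restricted to protein-coding genes was added later, because many of the lowered clusters were short non-coding RNAs.

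Alternatives chosen in advance were the trial number as a block, no filter, a filter at the median, a further quantile normalization, centring each array on its median, trended and robust eBayes, array weights, a fit of only the groups compared, a plain t-test on the same values, leaving out each array in turn, and for lists an estimated correlation, fry and the mean of all clusters of a gene. Fits without indicaxanthin array 3, with protein-coding genes only, and with unnamed clusters were added after the data were seen. Leaving out a control array leaves 1, whose spread is then taken from the other groups. Correlations of fold changes between comparisons with the same controls were set beside 100 simulated draws of unchanged groups against those controls.

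A control array behind the authors' deposited tables was worked out from their log2 ratios, F scores and sums of squares. The tables for indoline carboxylic acid-betacyanin and phenylalanine-betaxanthin rest on 3 arrays per group, and the control mean they imply, less the 2 control arrays analysed here, gives the level of 1 more. It entered no fit, and is used only for levels set beside the measured arrays and for the share of a shift found in it, which is its distance from the mean of the 2 controls over that of the treated mean. Where values are given with "or", the table of indoline carboxylic acid-betacyanin comes first. Clusters were called against the same 2 controls, which by itself leans the share upward, and the shares were added after the data were seen.

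The steps were tested on simulated data made from each cluster's mean over all arrays and its spread within groups, with 100 genes changed by a fold of 2 and 100 by a fold of 4 among 20291. For indoline carboxylic acid-betacyanin against control, limma recovered 26 and 74 of them with 3 false calls. For indicaxanthin against control it recovered 32 and 74, with 4 false calls, and for phenylalanine-betaxanthin against control 25 and 59, with 3 false calls. With the spread taken without indicaxanthin array 3, the numbers recovered were 70 and 97 (10 false calls), 60 and 99 (2 false calls), and 67 and 99 (12 false calls), in the same order. A shifted list was called by camera in 20 of 20 simulated runs, and 0 of 560 unshifted lists were called. The simulated genes were independent of each other and the lists were drawn at random. These runs therefore do not test false calls for lists whose genes move together. The analysis used R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.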

Results

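Yolk, oocyte, sperm and germ-line genes divided the 11 arrays more than the 4 groups did. The mean log2 level of the 6 yolk protein genes was 1.71 and 1.56 on the control arrays and 10.04, 10.01 and 10.07 on the arrays of phenylalanine-betaxanthin. It was 2.00, 3.17 and 1.67 with indoline carboxylic acid-betacyanin, called indoline-betacyanin below. With indicaxanthin it was 1.72 and 1.75 on arrays 1 and 2 and 10.09 on array 3. The 47 genes of the moulting cycle ran the other way, at a mean of 5.51 and 5.48 on the controls, 5.40, 5.25 and 3.67 with indicaxanthin, and 3.78, 3.89 and 4.06 with phenylalanine-betaxanthin. Over all clusters, indicaxanthin array 3 correlated at 0.818 and 0.826 with arrays 1 and 2 and at 0.99 to 0.994 with the phenylalanine-betaxanthin arrays, while other arrays of a group correlated at 0.983 to 0.992. The first principal component held 75.9% of the variance and set the phenylalanine-betaxanthin arrays (123.3 to 134.6) and indicaxanthin array 3 (137.5) apart from all other arrays (-80.9 to -68.6).

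**Figure D1:**
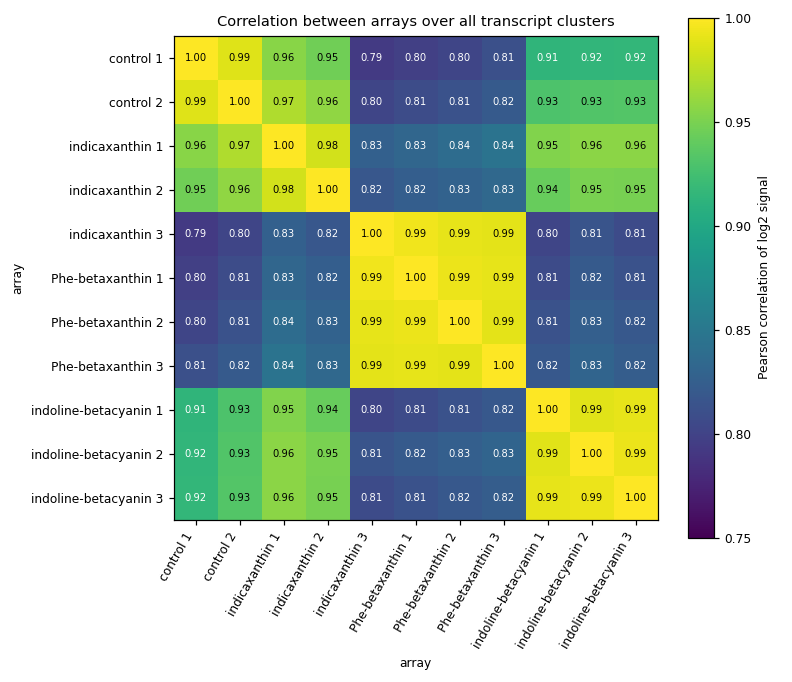
Pearson correlation of log2 signal between the 11 arrays over all transcript clusters. Indicaxanthin array 3 stands with the phenylalanine-betaxanthin arrays.

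The authors' deposited tables had 3728 clusters with an unadjusted p-value under 0.05 for indicaxanthin, 1921 for phenylalanine-betaxanthin and 4839 for indoline-betacyanin. Sums of squares in the authors' deposited tables matched 2 arrays per group for indicaxanthin and 3 for the other compounds, so the latter rest on 1 more control array than is analysed here. Fold changes in the authors' deposited table for indicaxanthin correlated at 0.926 with those of the arrays analysed here, and at 0.988 when indicaxanthin array 3 was left out. The correlation was 0.99 for the authors' deposited table of phenylalanine-betaxanthin and 0.826 for that of indoline-betacyanin. The values for indicaxanthin cover only its 3728 listed clusters and the others all 29317, so the compounds cannot be ranked by them. The third control implied by the authors' deposited tables had a mean yolk protein level of 10.09 (table of indoline-betacyanin) or 10.23 (table of phenylalanine-betaxanthin). Its oocyte genes stood at 7.88 or 8.37 by the authors' deposited tables, against 3.39 and 2.96 on the control arrays.

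By camera at the preset correlation, heat shock genes shifted up and histone genes down with indoline-betacyanin against the 2 controls (3 arrays against 2). Both list calls were lost with an estimated correlation, and only part of the genes of each list passed by limma. The gene ins-11, which encodes an insulin-like peptide, rose by 4.93 on the log2 scale (SE 0.23; adjusted p = 6.03e-06), and tsp-4, a tetraspanin, by 4.99 (SE 0.16; adjusted p = 2.61e-06). The gene thn-5, of the thaumatin family, rose by 5.02 (SE 0.25), cnp-3 by 4.29 (SE 0.17) and the nuclear hormone receptor nhr-6 by 4.02 (SE 0.57). Cuticle collagen genes col-93 and col-157 fell by 5.32 (SE 0.38; adjusted p = 3e-05) and 4.82 (SE 0.46). Other large increases were K10G6.5 (4.98, SE 0.29), Y73B6BL.37 (4.87, SE 0.67), F43C1.7 (4.44), Y58A7A.4 (4.29), Y38H6C.24 (4.27) and the non-coding F29G9.14 (4.04). The third control implied by the authors' deposited tables had ins-11 at 5.03 or 5.12, between 4.45 and 4.59 on the controls and 9.38 to 9.57 on the treated arrays, and col-93 at 6.17 or 7.07, against 1.44 to 1.85 on the treated arrays.

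**Figure D2:**
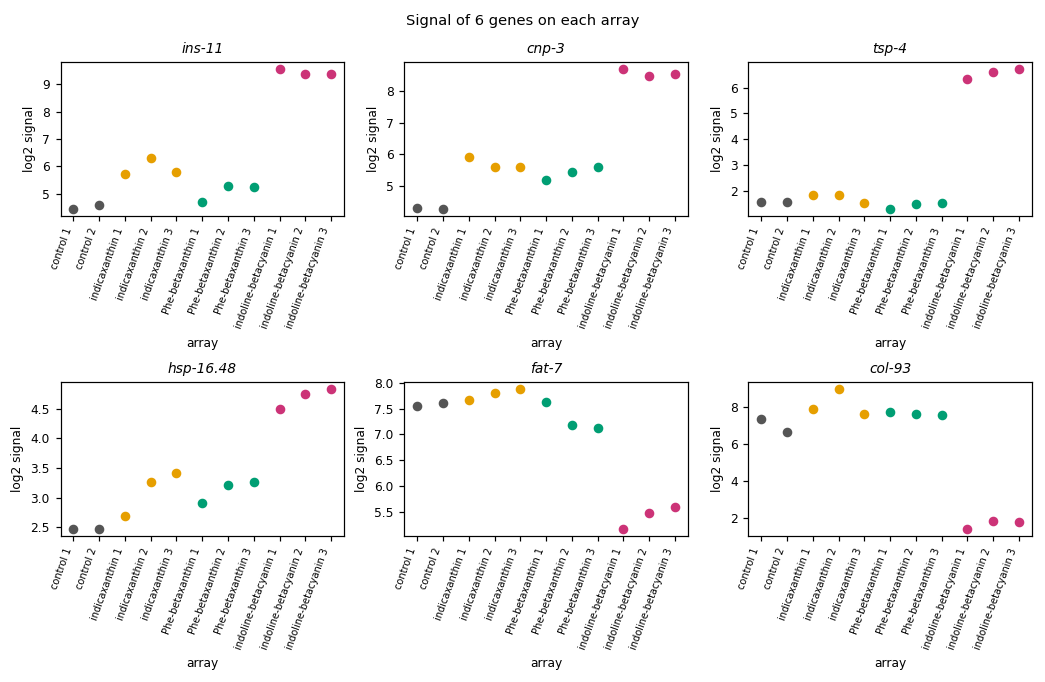
Log2 signal of ins-11, cnp-3, tsp-4, hsp-16.48, fat-7 and col-93 on each array. The indoline-betacyanin arrays lie apart from all others for each of the 6 genes.

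Heat shock genes went up with indoline-betacyanin: of 17 measured, 7 rose and 0 fell by limma, with the same counts when adjusted over the list alone (median log2 change 0.69; camera adjusted p = 0.000628; adjusted p = 0.623 with an estimated correlation). Among them were the small chaperone genes hsp-16.48 (2.21, SE 0.22), hsp-16.1 (2.07, SE 0.34) and hsp-16.2 (2.89, SE 0.70), the chaperone hsp-70 (1.76, SE 0.28) and the arsenite-inducible aip-1 (2.49, SE 0.37). The mean level of this list was 6.76 to 6.84 with indoline-betacyanin and 5.89 and 5.94 on the controls, but also 6.62 on indicaxanthin array 3, the array with high yolk levels in its group. It was 6.42 to 6.47 with phenylalanine-betaxanthin and 6.35 or 6.32 on the third control implied by the authors' deposited tables. Of 23 genes of the endoplasmic reticulum stress response, 4 rose and 0 fell, also when adjusted over the list alone. They included hsp-4, the BiP chaperone of that compartment (1.65, SE 0.23), dnj-27 (1.76, SE 0.27) and the stress sensor kinase pek-1 (1.38, SE 0.24). This list had a median of 0.24 (camera adjusted p = 0.0436; adjusted p = 0.677 with an estimated correlation). Its call ended without control array 1 (median 0.05; adjusted p = 0.183), without indoline-betacyanin array 1 (adjusted p = 0.075) and without indicaxanthin array 3 (adjusted p = 0.0664). It also ended under a further quantile normalization (adjusted p = 0.0895), array weights (adjusted p = 0.0689), the trial block (adjusted p = 0.0644) and the mean of all clusters of a gene (adjusted p = 0.054). Of 15 genes of the mitochondrial response 0 passed in limma, and hsp-6, its chaperone, had a log2 value of -0.15 that turned to 0.03 with each array centred on its median.

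By camera, the lists of collagens, histones, moulting and ribosomal proteins shifted down with indoline-betacyanin against the 2 controls. Whether a difference in developmental stage has a part in these shifts was not tested. Of 163 cuticle collagens 0 rose and 39 fell (46 when adjusted over the list alone), with a median of -0.70 (camera adjusted p = 2.27e-07; adjusted p = 0.677 with an estimated correlation). The gene col-159 was among the lowest (-3.57, SE 0.35). The mean collagen level was 3.95 to 4.18 on these arrays and 5.28 and 5.19 on the controls, but also 4.17 or 4.24 on the third control implied by the authors' deposited tables and 4.06 on indicaxanthin array 3. Of 41 histone genes 28 fell and 0 rose (32 adjusted over the list alone), such as his-31 (-2.28, SE 0.27), his-15 (-2.0, SE 0.20) and his-60 (-1.65, SE 0.18). The histone median was -0.97 (camera adjusted p = 7.37e-13; adjusted p = 0.511 with an estimated correlation). The mean histone level was 7.18 to 7.29, against 8.52 and 8.14 on the controls and 8.01 or 7.88 on the third control. Of 47 moulting genes 9 fell and 2 rose (10 and 3 adjusted over the list alone), at a median of -0.37 (camera adjusted p = 0.0211; adjusted p = 0.949 with an estimated correlation), a call that ended with the trial block (adjusted p = 0.0749). The hedgehog-related wrt-4 (-3.43, SE 0.60) and the moulting gene mlt-10 (-2.59, SE 0.51) were among them. The mean moulting level was 4.86 to 4.97, below 5.51 and 5.48 on the controls but above 3.72 or 3.7 on the third control and 3.67 on indicaxanthin array 3. On the third control mlt-10 stood at 2.43 or 2.46, beside 2.09 to 2.48 on the treated arrays. Of 78 ribosomal protein genes 8 fell, and 1 when adjusted over the list alone, with rpl-29 at -1.41 (SE 0.27) and rpl-36A at -0.55 (SE 0.13). The ribosomal median was -0.29 (camera adjusted p = 3.36e-08; adjusted p = 0.677 with an estimated correlation). Of yolk, oocyte and sperm genes, 0 of 6, 0 of 37 and 2 of 79 passed (limma; the list tests of camera, adjusted p = 0.768, 0.935 and 0.604), with the mean yolk level at 3.17 on array 2 and 2.00 and 1.67 on the others.

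Targets repressed by DAF-16, the transcription factor under insulin signalling, also fell with indoline-betacyanin: 6 of 15 fell and 1 rose, also when adjusted over the list alone (median -0.84; camera adjusted p = 0.0211; adjusted p = 0.511 with an estimated correlation). The intestinal peptide transporter pept-1 (-2.69, SE 0.25) and the fatty acid desaturase fat-7 (-2.16, SE 0.19) fell, and dod-20 rose (2.15, SE 0.47). The call of this list ended without control array 2 (adjusted p = 0.0535). Of 26 intestinal genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), with the acid phosphatase pho-1 at -1.88 (SE 0.17), the lysozyme-like lys-4 at -2.04 (SE 0.24) and the proton pump subunit vha-6 at -1.64 (SE 0.21). Their median was -0.38 (camera adjusted p = 0.00107; adjusted p = 0.656 with an estimated correlation). Of 282 immune effectors 25 rose and 42 fell (27 and 56 adjusted over the list alone), such as the C-type lectin genes clec-6 (3.45, SE 0.31) and clec-51 (-1.88, SE 0.14). The mean immune level was 3.55 to 3.68, against 3.83 on both controls and 3.46 or 3.45 on the third control. The immune median was -0.17 (camera adjusted p = 0.0401; adjusted p = 0.924 with an estimated correlation), and the call ended without control array 1 (adjusted p = 0.069), control array 2 (adjusted p = 0.0597) or indoline-betacyanin array 1 (adjusted p = 0.0749), and with the trial block (adjusted p = 0.0707). Neuronal genes were higher, with 9 of 61 up and 2 down (10 and 3 adjusted over the list alone), a median of 0.73 and camera adjusted p = 0.00107 (adjusted p = 0.949 with an estimated correlation). The touch channel gene mec-4 (1.96, SE 0.29) and the neuropeptide gene flp-28 (2.09, SE 0.39) rose, while the odorant receptor gene odr-10 fell (-1.68, SE 0.25). The mean neuronal level was 5.56 to 5.62 with indoline-betacyanin, 4.93 and 4.98 on the controls, and 3.70 on indicaxanthin array 3.

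Single detoxification and antioxidant genes changed strongly with indoline-betacyanin while their lists did not shift one way. Of 57 cytochrome P450 genes 7 rose and 3 fell (8 and 3 adjusted over the list alone), with cyp-36A1 at 3.91 (SE 0.13), cyp-14A5 at 2.60 (SE 0.23) and cyp-35C1 at 2.11 (SE 0.20), and camera adjusted p = 0.514. Of 98 conjugating enzymes 7 rose and 12 fell (7 and 14 adjusted over the list alone; camera adjusted p = 0.287), such as the glutathione transferases gst-19 (3.30, SE 0.22) and gst-24 (1.72, SE 0.23) and the glucuronosyltransferase ugt-38 (-3.60, SE 0.15). Of 29 antioxidant genes 3 rose and 3 fell (4 and 3 adjusted over the list alone), among them the superoxide dismutases sod-4 (2.35, SE 0.24), sod-5 (1.94, SE 0.25) and sod-1 (-1.08, SE 0.16) and the catalase ctl-3 (-1.54, SE 0.31). Of 17 metal-handling genes 4 rose and 0 fell, also adjusted over the list alone: the phytochelatin synthase pcs-1 (2.21, SE 0.20), the zinc transporter ttm-1 (1.21, SE 0.18), the ferritin ftn-1 (1.34, SE 0.26) and the zinc transporter cdf-1 (0.96, SE 0.28). The median of that list was 0.08, its mean -0.05 and its camera adjusted p 0.514. Of 48 lipid genes 5 rose and 4 fell, with the lysosomal lipase lipl-4 at 3.2 (SE 0.44) and the lipid-binding lbp-7 at -3.51 (SE 0.32). Of 30 genes activated by DAF-16, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of -0.10, a mean of 0.06 and camera adjusted p = 0.692. Pharyngeal muscle genes tni-4 (-2.36, SE 0.30) and myo-1 (-1.94, SE 0.28) fell, while the sarcomere gene unc-89 rose (1.5, SE 0.21). Of the 13 stress and ageing genes, skn-1, a regulator of phase II detoxification, rose by 0.55 (SE 0.13), and gst-4 (-1.05), mtl-1 (-2.95), hsf-1 (0.85), daf-16 (-0.19), daf-2 (0.37), sod-3 (0.56), vit-2 (1.81) and col-19 (-0.32) did not pass. For mtl-1 the treated arrays lay at 5.54 to 6.07, against 8.6 and 8.92 on the controls. For hsf-1 they lay at 6.17 to 6.35, against 5.3 and 5.48. The treated arrays of gst-4, daf-2, sod-3 and vit-2 did not overlap the controls either, while those of daf-16 and col-19 did. Indicaxanthin array 3, in neither group, widens the spread (mtl-1 3.15, against 9.49 and 9.81 on arrays 1 and 2). The third control had mtl-1 at 5.49 or 5.36 and hsf-1 at 6.68 or 6.95. It had ugt-38 at 0.54 or 0.65, ttm-1 at 6.38 or 6.36 and ctl-3 at 1.84 or 1.51. These lay at 1.0 to 1.14, 6.43 to 6.72 and 1.72 to 2.3 on the treated arrays. By contrast, it had cyp-36A1 at 2.28 or 2.81 and gst-19 at 1.2 or 1.38, far from 6.1 to 6.22 and 4.96 to 5.57 on the treated arrays.

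In all, 1617 clusters were higher and 1902 lower with indoline-betacyanin by limma, of 20291 tested. The total was 7173 (3472 higher, 3701 lower) without indicaxanthin array 3, which enters this comparison only through the spread, and 7459 with array weights. With each array centred on its median, which moved the median change of all clusters from 0.02 to 0.20, the split was 2513 and 1523. Of the lower ones 865 were non-coding RNAs other than pseudogenes. The largest decreases by the naming rule were T13A10.1 (-6.38, SE 0.57), T04D3.9 (-6.16, SE 0.61), ZK622.8 (-6.07), the 5S ribosomal RNA genes rrn-4.2 (-6.08, SE 0.96) and rrn-4.4 (-6.01), F36H12.5 (-5.86, SE 1.00), F49E11.12 (-5.54) and K02E11.10 (-5.51, SE 0.87). C24H11.11 (-6.21) and T28B4.6 (-5.53), both non-coding, stood at 1.37 or 1.32 and at 1.48 or 1.46 on the third control implied by the authors' deposited tables, against 7.42 to 8.13 on the controls. The third control had moved from the 2 controls by a median of 1.02 or 0.938 times the shift of the treated mean over the 1902 lower clusters, and by -0.0309 or -0.145 times over the 1617 higher ones. Over 1/2 of the shift was there for 1539 or 1505 of the lower and 269 or 219 of the higher clusters. Of the 75 named genes that passed, 18 had over 1/2 of their shift there by both tables and 50 had less by both. The former included wrt-4, mlt-10, rpl-29, ugt-38, ctl-3, pcs-1, ttm-1 and odr-10. Without control array 1 the total was 1865, and 11 of the 75 named genes past the threshold were no longer called: pek-1, dod-20, mlt-10, rpl-29, rpl-36A, flp-28, ctl-3, ftn-1, cdf-1, skn-1 and hsp-16.2 (adjusted p from 0.0513 to 0.28). With single other arrays of these groups left out, 2 to 4 genes among dod-20, rpl-36A, cdf-1, skn-1 and hsp-16.2 were lost (adjusted p from 0.0518 to 0.138).

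With phenylalanine-betaxanthin, genes of yolk, oocytes, sperm and the germ line shifted up by camera against the 2 controls (3 arrays against 2). Moulting, neuronal and muscle genes shifted down. Each of these list calls was lost with an estimated correlation, and only in the yolk list did every gene pass by limma. All 6 yolk protein genes rose, also adjusted over the list alone, with vit-6 at 9.06 (SE 2.25; adjusted p = 0.019), vit-4 at 8.71, vit-2 at 8.43 (SE 2.12), vit-3 at 8.37, vit-5 at 8.0 and vit-1 at 7.83. On the controls these genes lay at 1.19 to 2.67, near the filter level of 1.523, so the size of these changes is uncertain. Of 37 oocyte and eggshell genes 32 rose and 1 fell (34 and 1 adjusted over the list alone), such as the eggshell proteoglycan gene cpg-3 (7.38, SE 1.82), perm-4 (6.5, SE 1.54) and the RNA-binding puf-3 (6.0, SE 1.49). Of 79 sperm genes 54 rose and 0 fell (60 and 0 adjusted over the list alone), with nspd-10 at 6.63 (SE 1.55), nspd-7 at 3.74 and spe-36 at 1.35 (SE 0.19). Of 40 germ-line genes 35 rose and 0 fell (38 and 1 adjusted over the list alone), with the P granule gene pgl-1 at 4.73 (SE 1.09), the meiotic synapsis gene syp-2 at 3.43 (SE 0.71) and the meiotic endonuclease gene spo-11 at 2.87 (SE 0.64). The medians were 8.4, 5.41, 1.75 and 2.86 (camera adjusted p = 0.00575, 2.33e-08, 1.73e-10 and 5.8e-10; adjusted p = 0.697 for each with an estimated correlation). Indicaxanthin array 3 had levels like these, and so did the third control implied by the authors' deposited tables, where vit-2 stood at 10.29 or 10.76, against 1.58 and 1.81 on the controls and 10.08 to 10.23 on the treated arrays.

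**Figure D3:**
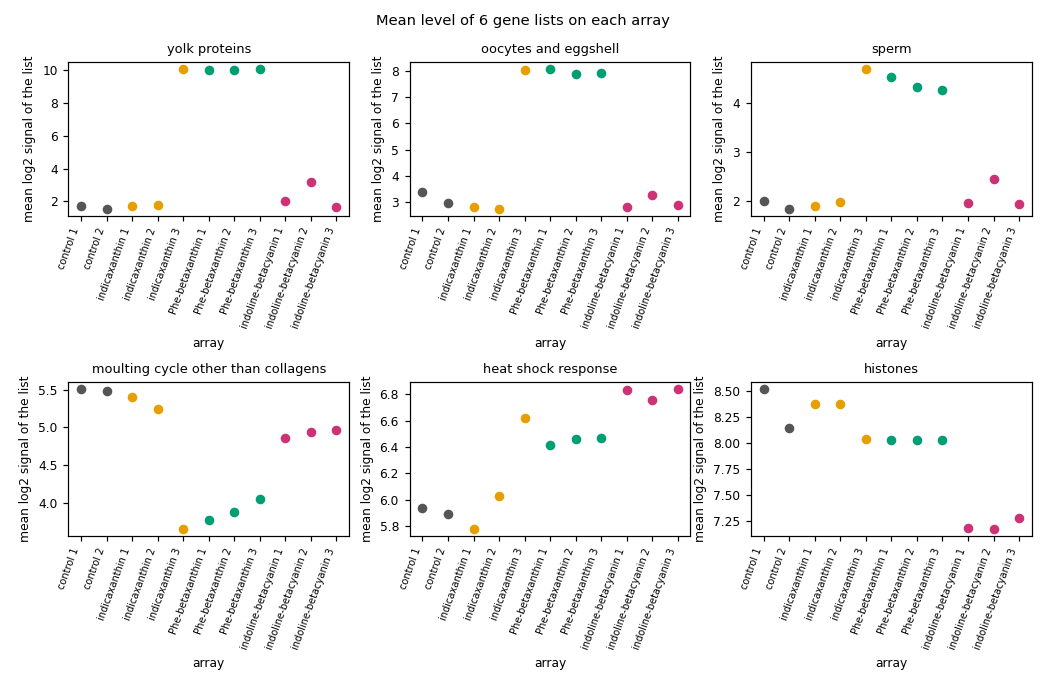
Mean log2 signal of 6 gene lists on each array. Yolk, oocyte and sperm genes are high on the phenylalanine-betaxanthin arrays and on indicaxanthin array 3.

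Of 47 moulting genes 29 fell and 0 rose with phenylalanine-betaxanthin (33 adjusted over the list alone), including the apical matrix genes noah-2 (-3.23, SE 0.77) and noah-1 (-2.89, SE 0.71) and abu-6 (-2.22, SE 0.26). The moulting median was -1.65 (camera adjusted p = 4.57e-06; adjusted p = 0.697 with an estimated correlation). Cuticle collagens went both ways, 33 up and 71 down of 163 (37 and 81 adjusted over the list alone). They ranged from col-143 (8.62), col-119 (7.83) and the adult collagen col-19 (5.70, SE 1.76) to col-2 (-8.13, SE 2.04), col-37 (-7.20), col-123 (-7.15), col-36 (-7.13) and col-158 (-6.81). Their median was -1.26 (camera adjusted p = 0.0318; adjusted p = 0.697 with an estimated correlation), and the call ended without control array 1 (adjusted p = 0.0875) or phenylalanine-betaxanthin array 1 (adjusted p = 0.0789). The ground-like genes grl-20 (-7.55), grl-23 (-7.49) and grl-19 (-7.20) and C35A5.11 (-7.36) fell as well, while F57C2.4 (9.21, SE 2.27) and D1054.10 (8.19) rose. Of 61 neuronal genes 33 fell and 0 rose (34 adjusted over the list alone), with the neuropeptide genes flp-7 (-3.56, SE 0.83) and flp-11 (-2.34, SE 0.46) and odr-10 (-1.51, SE 0.25). The neuronal median was -1.01 (camera adjusted p = 6.06e-06; adjusted p = 0.697 with an estimated correlation). Of 31 muscle genes 15 fell and 0 rose, also adjusted over the list alone, such as the attachment gene deb-1 (-1.46, SE 0.37) and dim-1 (-0.95, SE 0.23). The muscle median was -0.62 (camera adjusted p = 0.00864; adjusted p = 0.697 with an estimated correlation). On indicaxanthin array 3 the mean moulting level was 3.67 and the mean neuronal level 3.70, beside 3.78 to 4.06 and 3.71 to 3.75 with phenylalanine-betaxanthin.

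Heat shock genes shifted up by camera with phenylalanine-betaxanthin, with 7 of 17 up and 1 down by limma (10 and 3 adjusted over the list alone), a median of 0.68 and camera adjusted p = 0.035 (adjusted p = 0.697 with an estimated correlation). The co-chaperone dnj-13 (0.68, SE 0.19) and hsp-43 (1.12, SE 0.35) rose and hsp-12.3 (-3.39, SE 0.93) fell. The call ended without control array 2 (adjusted p = 0.053) or phenylalanine-betaxanthin array 3 (adjusted p = 0.0572). Of 48 lipid genes 20 fell and 3 rose (21 and 3 adjusted over the list alone), with the acyl-CoA synthetase acs-2 at -6.86 (SE 1.43) and the elongase elo-6 at -0.76 (SE 0.19). The lipid median was -0.58 (camera adjusted p = 0.00596; adjusted p = 0.697 with an estimated correlation). Of 57 cytochrome P450 genes 13 fell and 5 rose (6 and 3 adjusted over the list alone), such as cyp-37A1 (-2.35, SE 0.52) and cyp-13B2 (1.35, SE 0.29). The median was -0.47 (camera adjusted p = 0.0465; adjusted p = 0.711 with an estimated correlation), a call that ended without control array 2 (adjusted p = 0.232) or phenylalanine-betaxanthin arrays 1 (adjusted p = 0.0526) or 3 (adjusted p = 0.0673). It also ended with no filter (adjusted p = 0.0533), a further quantile normalization (adjusted p = 0.0523) and the trial block (adjusted p = 0.0787). Oxidative phosphorylation had 16 down and 6 up of 67 (13 and 6 adjusted over the list alone; median -0.34; camera adjusted p = 0.0213; adjusted p = 0.697 with an estimated correlation). This call was lost without control array 1 (adjusted p = 0.0878). The proteasome had 2 up of 33, and 0 adjusted over the list alone (median 0.21; camera adjusted p = 0.0465; adjusted p = 0.697 with an estimated correlation). This call was lost without control array 2 (adjusted p = 0.11), without phenylalanine-betaxanthin array 1 (adjusted p = 0.105) or 3 (adjusted p = 0.0572), and without indicaxanthin array 3 (adjusted p = 0.0971), and with array weights (adjusted p = 0.0591) or the trial block (adjusted p = 0.0794). Of the stress and ageing genes, hsf-1, the heat shock transcription factor, rose by 1.40 (SE 0.50) and hsp-4 by 0.69 (SE 0.23). The superoxide dismutase sod-3 fell by 3.57 (SE 1.07) and gst-4 by 1.77 (SE 0.53). The genes hsp-16.2 (1.65), mtl-1 (-3.52), daf-2 (0.58), daf-16 (-0.24), skn-1 (-0.29), fat-7 (-0.26) and hsp-6 (0.49) did not pass. Of these, only fat-7 had treated arrays that overlapped the controls. For mtl-1 the treated arrays lay at 4.78 to 5.53, against 8.6 and 8.92 on the controls and 5.49 or 5.36 on the third control. Indicaxanthin array 3, in neither group, widens the spread (mtl-1 3.15, against 9.49 and 9.81 on arrays 1 and 2). On the control implied by the authors' deposited tables sod-3 stood at 3.35 or 3.24. It lay at 7.07 and 7.16 on the controls and at 3.44 to 3.69 on the treated arrays. The implied control had hsf-1 at 6.68 or 6.95, hsp-4 at 5.38 or 5.35 and gst-4 at 5.74 or 5.77. These lay at 6.7 to 6.87, 5.43 to 5.54 and 5.7 to 5.95 on the treated arrays. Its mean levels were 6.35 or 6.32 (heat shock), 2.69 or 2.61 (cytochrome P450) and 8.32 or 8.28 (proteasome). The treated arrays had 6.42 to 6.47, 2.65 to 2.77 and 8.23 to 8.35. Whether the compound adds to these shifts was not tested.

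By limma, 4517 clusters were higher and 4524 lower with phenylalanine-betaxanthin, and 5727 and 3268 with each array centred on its median, when the median change of all clusters went from -0.05 to 0.12. With the trial block, 39 of the 61 named genes that passed were still called and 22 were lost (limma adjusted p from 0.05 to 0.105). The total was 12380 without indicaxanthin array 3, 12754 with array weights and 3658 (1650 higher, 2008 lower) with the trial block. It fell to 1156 without control array 1, 1934 without control array 2, and 2625, 2569 and 4914 without phenylalanine-betaxanthin arrays 1, 2 and 3. Of the 61 genes named for this comparison that passed, such as vit-6 and cpg-3, 5 passed without control array 1, 7 without control array 2, and 19, 17 and 51 without arrays 1, 2 and 3 of the treated group. The others had an adjusted p from 0.051 to 0.18.

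Indicaxanthin had few transcripts above the controls, and 1194 of the 1258 changed clusters were lower (3 arrays against 2). The antimicrobial peptide genes cnc-2 and nlp-28 rose by 2.14 (SE 0.26; adjusted p = 0.00083) and 1.51 (SE 0.22; adjusted p = 0.0028), and the insulin-like ins-11 by 1.42 (SE 0.23; adjusted p = 0.00509). So did dct-8 (3.15, SE 0.69), nspc-7 (2.45, SE 0.40), R09E10.13 (2.44, SE 0.33), T10C6.15 (1.88, SE 0.21), ZK669.3 (1.61, SE 0.37), nspe-1 (1.53, SE 0.33), cnp-3 (1.42, SE 0.17) and the sperm gene spe-27 (1.39, SE 0.25). On the third control implied by the authors' deposited tables cnc-2 stood at 7.28 or 7.17 and nlp-28 at 9.01 or 8.98. They lay at 6.93 to 7.87 and 8.69 to 9.33 with indicaxanthin and at 5.21 to 5.34 and 7.47 to 7.6 on the controls. The gene dct-8 stood at 1.00 and 1.33 on the controls, at 2.71 and 4.71 on indicaxanthin arrays 1 and 2 and at 5.52 on array 3, the array with high yolk levels, but at 6.89 or 6.35 on the third control. Of 282 immune effectors 2 rose and 16 fell, also adjusted over the list alone (median 0.01; camera adjusted p = 0.862).

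Of the lower clusters with indicaxanthin 842 were non-coding RNAs other than pseudogenes, 699 of them under 200 nt. They included M01A8.4 (-4.95, SE 0.34; adjusted p = 4.06e-05), C24H11.11 (-4.84, SE 0.57), T28B4.6 (-4.65, SE 0.29), F23C11.2 (-4.64, SE 0.19), D2024.17 (-4.63), Y38C1AA.18 (-4.56), T04D3.9 (-4.54), C39E9.17 (-4.53), F48B9.10 (-4.50) and C31H5.9 (-4.50). Among protein-coding genes, Y17D7C.1 (-4.41, SE 0.49), the histone gene his-54 (-3.71, SE 0.36), the pheromone receptor gene srg-36 (-3.51, SE 0.29), ugt-38 (-3.45, SE 0.15), abu-6 (-1.95, SE 0.26) and the catalase ctl-3 (-1.28, SE 0.31) fell. The gene ugt-38 stood at 0.54 or 0.65 and srg-36 at 0.70 or 1.41 on the third control implied by the authors' deposited tables, against 4.42 to 4.88 and 5.15 to 5.49 on the controls. The third control had moved from the 2 controls by a median of 1.2 or 1.09 times the shift with indicaxanthin over the lower clusters and 1.03 or 0.874 times over the higher ones. Of the 30 named genes that passed, 27 had over 1/2 of their shift there by both tables. With protein-coding genes only, 14 were higher and 193 lower.

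Of the 29 lists, 4 shifted with indicaxanthin, and each moved with array 3. Sperm genes had a median of 0.85 (1 of 79 up; camera adjusted p = 8.05e-05), and oocyte genes 1.52 (0 of 37 by limma; camera adjusted p = 0.0345). Medians were 1.12 for germ-line genes (0 of 40; camera adjusted p = 0.00278) and -0.75 for moulting genes (1 of 47 down, abu-6; camera adjusted p = 0.00101), with the same counts adjusted over the list alone. Each had an adjusted p = 0.949 with an estimated correlation. Without array 3 the medians were 0.02 (adjusted p = 0.972), -0.40 (adjusted p = 0.00364), -0.01 (adjusted p = 0.628) and -0.16 (adjusted p = 0.256). The oocyte call also ended without control array 2 (median 1.21; adjusted p = 0.212), and under a further quantile normalization (adjusted p = 0.105) and median centring (adjusted p = 0.259), where the germ-line call ended too (adjusted p = 0.103). The oocyte call ended with no filter (adjusted p = 0.0565) and with the trial block (adjusted p = 0.378), as did the germ-line call with the block (adjusted p = 0.075). With array weights all 4 calls ended (adjusted p = 0.952, 0.287, 0.998 and 0.488). Without array 3, cytochrome P450 genes, conjugating enzymes, metal-handling genes (medians 0.24, 0.24 and 0.45; adjusted p = 0.0181, 0.0181 and 0.0167) and embryonic genes (median -0.26; adjusted p = 0.0181) were called instead. Of 25 genes of the embryo 3 fell and 0 rose with all arrays (5 and 0 adjusted over the list alone), sdz-19 (-2.80, SE 0.26), pes-1 (-1.67, SE 0.21) and hlh-27 (-1.47, SE 0.31). The list had camera adjusted p = 0.0596 and fry adjusted p = 0.0128. None of the 13 stress and ageing genes passed in limma with indicaxanthin: hsp-16.2 stood at 0.87, hsf-1 at 0.33, hsp-4 at 0.26, fat-7 at 0.21, hsp-6 at 0.12, daf-2 at 0.06, and skn-1 at -0.21. The log2 values were gst-4 -0.25, sod-3 -1.07, mtl-1 -1.28, vit-2 3.16 (SE 2.12), col-19 1.35, and daf-16 -0.13, or 0.04 with each array centred. Array 3 carried several of these. Without it the values were gst-4 0.42, sod-3 0.34, mtl-1 0.89, vit-2 0.45, col-19 -0.85, hsf-1 -0.31, daf-2 -0.18 and hsp-6 -0.10, none of them past the threshold.

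**Figure D4:**
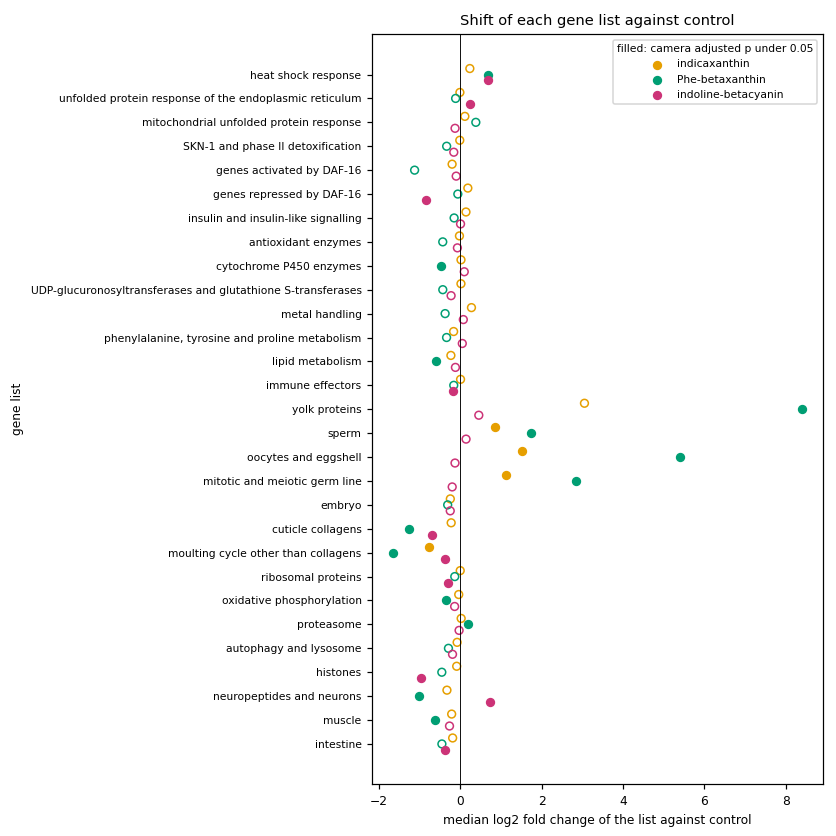
Median log2 change of each of 29 gene lists against control for the 3 betalains. Filled points have a camera adjusted p under 0.05 at the preset correlation.

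With indicaxanthin 64 clusters were higher and 1194 lower by limma, or 213 and 965 with each array centred on its median, when the median change of all clusters went from 0.05 to 0.21. The total was 776 without control array 1 and 2127 (616 higher, 1511 lower) without indicaxanthin array 3. Without control array 1, 8 of the 30 named genes that passed were lost, dct-8, nspc-7, ZK669.3, nspe-1, ins-11, ctl-3, spe-27 and hlh-27 (adjusted p from 0.0591 to 0.364). From 1 to 5 genes among dct-8, ZK669.3, nspe-1, ctl-3 and hlh-27 were lost without control array 2, indicaxanthin array 1 or array 2 (adjusted p from 0.0544 to 0.102).

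Against the same 2 controls, 1046 clusters were lower with each of the 3 betalains, 730 of them non-coding RNAs other than pseudogenes, and 32 were higher with each. Indicaxanthin and phenylalanine-betaxanthin shared 1188 lower clusters, indicaxanthin and indoline-betacyanin 1049, and phenylalanine-betaxanthin and indoline-betacyanin 1471. Shared higher clusters were 54, 37 and 256, and 0, 13 and 248 were called in opposite directions. Calls independent of each other would share 14.2, 5.1 and 360 higher clusters and 266, 112 and 424 lower ones, so 256 lies below its value. Calls against the same controls are not independent, so a count above these values shows no shared response. These counts were not set against a value for unchanged groups. All 3 comparisons used the same control arrays, which alone gives a correlation of fold changes of 0.599 in simulated draws. The measured correlations were 0.861, 0.524 and 0.298, the first falling to 0.324 without indicaxanthin array 3. The simulated groups held no change, and changes particular to a single compound lower a correlation. A value under 0.599 therefore does not show that nothing was shared beyond the controls. Covariances of fold changes were 0.995, 0.354 and 0.402, against 0.11 in the draws. The first fell to 0.3 without indicaxanthin array 3. No draws were made without that array, so 0.324 and 0.3 have no value to be set against. The draws were of unchanged groups and hold no offset of the 2 controls from all other samples. A correlation above 0.599 or a covariance above 0.11 therefore does not tell a shared response from such an offset. The 730 shared non-coding RNAs had a median log2 level of 3.91 and 3.61 on the controls, 1.55 to 1.90 on the betalain arrays, and 1.44 or 1.66 on the third control implied by the authors' deposited tables.

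For the mean of the 3 betalains, ZK105.1 (3.70, SE 0.85), dct-8 (3.15, SE 0.59), Y38H6C.24 (2.87, SE 0.39), the caenacin gene cnc-7 (2.77, SE 0.58) and F43C1.7 (2.72, SE 0.39) had the largest increases by the naming rule, which takes only clusters past the threshold. C24H11.11 (-5.77, SE 0.49), T04D3.9 (-5.61, SE 0.53), rrn-4.2 (-5.53, SE 0.82), rrn-4.4 (-5.50, SE 0.81) and ZK622.8 (-5.50, SE 0.65) had the largest decreases by that rule. ZK105.1 stood at 9.39 or 9.52 on the third control implied by the authors' deposited tables, against 3.52 and 4.59 on the controls. Of 17 heat shock genes 5 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00442). Of 41 histone genes 8 fell (21 adjusted over the list alone; camera adjusted p = 1.04e-05), and of 163 collagens 15 fell and 1 rose (6 and 0 adjusted over the list alone; camera adjusted p = 0.000177). Of 26 intestinal genes 7 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00442). These 4 lists each had an adjusted p = 0.756 with an estimated correlation. Yolk, sperm, oocyte and germ-line genes shifted up and moulting genes down, with medians of 4.02, 0.96, 2.22, 1.37 and -1.22 (camera adjusted p = 0.0356, 8.67e-06, 0.000301, 0.000177 and 9.04e-06; adjusted p = 0.756 with an estimated correlation). The high yolk levels were those of phenylalanine-betaxanthin and indicaxanthin array 3. In all 551 clusters were higher and 1705 lower by limma, or 1642 and 1403 with each array centred on its median, with 1070 in total without control array 1 and 8166 without indicaxanthin array 3. ZK105.1, dct-8 and cnc-7 were lost without control array 1 (adjusted p from 0.115 to 0.269) or control array 2 (adjusted p from 0.055 to 0.0946).

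The lists of lipid metabolism, ribosomal proteins, oxidative phosphorylation and muscle also shifted down for the mean of the betalains. Their medians were -0.41, -0.14, -0.18 and -0.35 (camera adjusted p = 0.0154, 0.0031, 0.0356 and 0.0228; adjusted p = 0.756, 0.756, 0.768 and 0.756 with an estimated correlation). Without control array 1 the ribosomal (adjusted p = 0.514) and oxidative phosphorylation calls (adjusted p = 0.296) ended. Without control array 2 it was those of lipid metabolism (adjusted p = 0.213), yolk (adjusted p = 0.107), muscle (adjusted p = 0.119) and the intestine (adjusted p = 0.0756). The oxidative phosphorylation call also ended without indicaxanthin array 3 (adjusted p = 0.0671), indoline-betacyanin array 1 (adjusted p = 0.0815) or phenylalanine-betaxanthin array 2 (adjusted p = 0.0502). Median centring ended it at a median of -0.006 (adjusted p = 0.225), as did the trial block (adjusted p = 0.0724) and array weights (adjusted p = 0.0518). The yolk call ended under median centring (adjusted p = 0.164), the trial block (adjusted p = 0.0724) and a further quantile normalization (adjusted p = 0.0618). The ribosomal median turned to 0.03 under a further quantile normalization (adjusted p = 0.672) and to 0.04 under median centring (adjusted p = 0.355).

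Phenylalanine-betaxanthin and indicaxanthin are both betaxanthins and differ in the amino acid joined to betalamic acid, phenylalanine or proline, and both were given at 25 uM for 48 h. No cluster differed between them by limma (0 of 20291; smallest adjusted p = 0.14), while 6636 had an unadjusted p under 0.05, where 1015 would be by chance. The plain t-test also gave 0 (812 with an unadjusted p under 0.05), as did the trial block (6318) and trended robust limma. Among the smallest p-values were the values for drd-10 (3.41, 95% interval 2.31 to 4.51), K12B6.11 (1.85, 1.40 to 2.31), Y53G8AR.10 (1.7, 1.12 to 2.28), K12H6.2 (1.08, 0.75 to 1.41) and F29G9.14 (0.94, 0.56 to 1.32) on one side. On the other side were srlf-3 (-1.91, -2.61 to -1.21), F16C3.2 (-1.63, -2.24 to -1.02), C50F7.5 (-1.54, -2.14 to -0.93), the hedgehog-related grd-6 (-1.40, -1.86 to -0.94) and F13H6.12 (-1.17, -1.56 to -0.79), each with an adjusted p of 0.14. For vit-2 the difference was 5.27 with an SE of 1.90, so that the interval of a yolk gene spans several log2 units. Indicaxanthin array 3 widened the spread: without it 5402 clusters were higher and 5776 lower with phenylalanine-betaxanthin, and array weights gave 5452 and 5855. By camera 18 lists differed, and 0 with fry or with an estimated correlation (adjusted p = 0.508 at best). Among them were yolk (median 5.49; camera adjusted p = 0.000902), oocyte (3.9; adjusted p = 1.28e-11) and germ-line genes (1.84; adjusted p = 4.12e-13). Sperm (1.08; camera adjusted p = 1.37e-10), moulting (-0.97; adjusted p = 3.52e-05) and neuronal genes (-0.83; adjusted p = 4.76e-09) differed too. Adjusted over the list alone, 6 of 6 yolk genes, 33 of 37 oocyte genes and 34 of 40 germ-line genes were higher and 1 oocyte gene lower, and 3 metal-handling genes were higher and 5 lower.

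Indoline-betacyanin, a betacyanin, was compared with indicaxanthin at the same dose and time. The gene tsp-4 was higher by 4.84 (SE 0.15; adjusted p = 1.83e-06), Y73B6BL.37 by 4.81 (SE 0.60), K10G6.5 by 4.62 (SE 0.26), C54E10.11 by 3.94 (SE 0.27) and F29G9.14 by 3.93 (SE 0.17). The collagen genes col-93 (-6.47, SE 0.34) and col-159 (-4.59, SE 0.31) were lower, as were K02E11.10 (-4.16, SE 0.78), spig-20 (-3.89, SE 0.94) and F23A7.8 (-3.86, SE 0.69). Of 17 heat shock genes 4 were higher and 0 lower (6 adjusted over the list alone), with hsp-16.48 at 1.57 (SE 0.20). Of 23 endoplasmic reticulum stress genes 5 were higher and 0 lower, also adjusted over the list alone, with hsp-4 at 1.39 (SE 0.21). Their camera adjusted p was 0.00233 and 0.00458 (adjusted p = 0.684 for both with an estimated correlation). Histones were lower (22 of 41 genes, 30 adjusted over the list alone; median -0.92; camera adjusted p = 1.47e-13). So were collagens (25 of 163, 32 adjusted over the list alone; median -0.74; camera adjusted p = 2.74e-07) and ribosomal proteins (15 of 78, 26 adjusted over the list alone; median -0.31; camera adjusted p = 1.43e-11). The 3 lists had adjusted p = 0.461, 0.684 and 0.684 with an estimated correlation. Neuronal genes were higher, 19 of 61 up and 2 down (26 and 3 adjusted over the list alone; median 1.08; camera adjusted p = 2.86e-07; adjusted p = 0.791 with an estimated correlation), with mec-4 at 2.46 (SE 0.26). The mean neuronal level was 5.02 and 5.22 on indicaxanthin arrays 1 and 2 and 3.70 on array 3. In all 1985 clusters were higher and 897 lower by limma. The total was 5646 without indicaxanthin array 3 and 1705, 1745 and 1678 without indoline-betacyanin arrays 1, 2 and 3, and spig-20 was lost without array 1 (adjusted p = 0.0922) or 3 (adjusted p = 0.0743).

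DAF-16-repressed (median -0.94; camera adjusted p = 0.00148), immune (-0.14; camera adjusted p = 0.0328) and intestinal genes (-0.31; camera adjusted p = 0.00458) were also lower with indoline-betacyanin than with indicaxanthin (adjusted p = 0.181, 0.844 and 0.684 with an estimated correlation). Sperm, oocyte and germ-line genes had medians of -0.82, -1.85 and -1.23 (camera adjusted p = 0.00231, 0.025 and 3.05e-05; adjusted p = 0.886 with an estimated correlation). Without indicaxanthin array 3 they were 0.11 (adjusted p = 0.24), 0.18 (adjusted p = 0.0804) and -0.19 (adjusted p = 0.12). The immune call ended without indicaxanthin array 1 (adjusted p = 0.0726) or 2 (adjusted p = 0.257) or indoline-betacyanin array 1 (adjusted p = 0.0601). The intestinal call ended without indicaxanthin array 1 (adjusted p = 0.0512), and that of endoplasmic reticulum stress without indicaxanthin array 2 (adjusted p = 0.0514).

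Between indoline-betacyanin and phenylalanine-betaxanthin, also at 25 uM for 48 h, 4768 clusters were higher and 4824 lower by limma. The lectin gene clec-61 (7.53, SE 1.09), col-2 (7.18, SE 1.82), acs-2 (7.03, SE 1.28), col-123 (6.93, SE 1.74) and C35A5.11 (6.8, SE 1.82) were higher. The genes vit-5 (-8.36, SE 2.0), vit-4 (-8.2, SE 1.96), col-143 (-8.05, SE 1.89), vit-3 (-7.96, SE 1.83) and the eggshell gene cpg-1 (-7.81, SE 1.91) were lower (adjusted p from 0.00129 to 0.0144). Of 61 neuronal genes 47 were higher and 2 lower, also adjusted over the list alone, and of 40 germ-line genes 39 were lower and 0 higher (40 adjusted over the list alone). Their camera adjusted p was 8.76e-10 and 2.17e-11 (adjusted p = 0.748 with an estimated correlation). DAF-16-activated genes were higher (17 of 30 up, 4 down; median 1.1; camera adjusted p = 0.0173) and DAF-16-repressed genes lower (10 of 15 down, 1 up; median -1.7; camera adjusted p = 0.00699). The latter list holds the yolk genes vit-2 and vit-5. The counts were the same adjusted over the list alone, with adjusted p = 0.748 and 0.393 with an estimated correlation. Cytochrome P450 genes were higher (17 of 57 up, 4 down; 14 and 4 adjusted over the list alone), as were lipid genes (19 of 48 up, 5 down) and moulting genes (21 of 47 up, 2 down), both also adjusted over the list alone. Histones were lower (20 of 41 down, 6 up; 21 and 6 adjusted over the list alone). The camera adjusted p was 0.00228, 0.0226, 0.0262 and 8.43e-05 (adjusted p = 0.748 with an estimated correlation). Camera also called endoplasmic reticulum stress (12 of 23 up, 3 down; adjusted p = 0.0439), the mitochondrial response (8 of 15 down; 0.0424), the proteasome (3 of 33 down; 0.0226) and muscle (12 of 31 up, 4 down; 0.0339). Each had an adjusted p = 0.748 with an estimated correlation and ended in at least 1 fit with an array left out. The first ended without indoline-betacyanin array 1 (adjusted p = 0.061) or phenylalanine-betaxanthin array 2 (adjusted p = 0.054), the next lists without phenylalanine-betaxanthin array 1 (adjusted p = 0.0541 and 0.0529), and muscle without indoline-betacyanin array 1 (adjusted p = 0.0521). Without indicaxanthin array 3, which is in neither group, the first 3 ended as well (adjusted p = 0.0608, 0.103 and 0.0665). Array weights ended the first (adjusted p = 0.059) and the mitochondrial call (adjusted p = 0.0756), and the trial block ended the first (adjusted p = 0.0529). Yolk levels were 1.67 to 3.17 with indoline-betacyanin and 10.01 to 10.07 with phenylalanine-betaxanthin. Genes activated by DAF-16 had means of 6.27 to 6.36 with indoline-betacyanin, near 6.26 and 6.27 on the controls. Their means were 5.21 to 5.35 with phenylalanine-betaxanthin and 5.2 or 5.1 on the third control. Moulting means were 4.86 to 4.97 with indoline-betacyanin, below 5.51 and 5.48 on the controls, and 3.78 to 4.06 with phenylalanine-betaxanthin.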

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

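The tests of explanations and the other splits of the arrays in this part were chosen only after the results they bear on were seen. The third control array implied by the authors' deposited tables entered no comparison, and its germ-line signal stood far above the control arrays. Its mean log2 level of yolk proteins was 10.09 by the table of indoline-betacyanin and 10.23 by that of phenylalanine-betaxanthin, against 1.71 and 1.56 on the controls. For sperm genes it was 4.43 and 4.45 (controls 2.00 and 1.84), for oocyte genes 7.88 and 8.37 (controls 3.39 and 2.96), and for mitotic and meiotic germ-line genes 6.28 and 6.30 (controls 3.14 and 3.06). The array is inferred: the levels worked out from these tables correlated at 0.983 and differed by a median of 0.217, and the sums of squares rebuilt with it correlated at 0.952 and 0.976 with those in the authors' deposited tables.

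Indicaxanthin array 3 stood apart from arrays 1 and 2. A swap with a phenylalanine-betaxanthin array is argued against, since none of these correlated above 0.845 with indicaxanthin arrays 1 or 2, where a partner out of place would be near the 0.983 these reach with each other. A single wrong label stays open: 90 clusters differed over 2-fold from the mean of the phenylalanine-betaxanthin arrays, within the 57 to 121 by which each of those differs from the others of its group. A later developmental stage of this sample is also open. Of the 162 yolk, sperm, oocyte and germ-line genes, 83.3% (135) were over 2-fold above both other arrays and 0 were as far below, and 31 of 47 moulting genes were over 2-fold lower and 0 higher. These tests do not tell a late sample from a wrong label, and no effect of indicaxanthin itself could be separated within the group.

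Whether treatment is the whole cause of the difference of phenylalanine-betaxanthin from the controls stays open. The third control, as implied, had moved from the control arrays by a median of 1.02 times the shift of the treated mean over the 9041 changed clusters (quartiles 0.873 to 1.17; 1.03 by the table of phenylalanine-betaxanthin), and in the same direction for 98.9% of them. A difference in developmental stage between samples is a candidate explanation that stays open: 78.4% of the 162 germ-line and yolk genes (127) were higher and 1 lower, and 29 of 47 moulting genes were lower and 0 higher. The third control is 1 inferred array whose own label could be wrong, so it excludes nothing, and whether an effect of the compound lies beneath this was not tested.

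For the 1046 clusters lower with each of the 3 betalains, treatment as the whole cause stays open for the same reason. The third control implied by the tables had moved by a median of 1.15 times their mean shift (quartiles 0.995 to 1.32; 1.04 by the table of phenylalanine-betaxanthin). An offset of whole arrays as the whole cause is argued against, since 858 clusters were lower in all 3 after centring each array on its median. Centring moves every cluster of an array by the same amount, so it cannot test other effects of the normalization. A difference in RNA size selection or purification between the 2 control samples and all others may contribute and stays open: of the non-coding RNAs, 25.9% of those under 100 nt (193 of 746) were lower in all 3, against 16.8% of those of 200 nt or more (132 of 787) and 1.77% of protein-coding clusters.

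Each comparison of 3 arrays with 3 has 10 splits, too few to give a share under 0.05. For genes, the count was 0 between the betaxanthins, which no split can fall below, with 28 as the highest of the other splits. It was 2882 between indoline-betacyanin and indicaxanthin with 0 as the highest other (1 split), and 9592 between indoline-betacyanin and phenylalanine-betaxanthin with 0 as the highest other (1 split). Every other split mixes both groups, so a large difference between them enters the spread and holds the other counts down. The gap to 0 is therefore no evidence against chance. For lists, the counts were 18 with 21 as the highest other (4 splits as large), 12 with 21 (9 splits) and 16 with 13 (1 split). The 28 clusters came from a single split, which set phenylalanine-betaxanthin arrays 1 and 2 together with indicaxanthin array 3.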

How the results depend on the processing

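The settings without indicaxanthin array 3, with protein-coding genes only and with unnamed clusters were chosen after the data were seen; all others were planned. Arrays hold no counts, so depth is given by signal over background: array medians were 1.95 to 2.17 and the highest signals 11.38 to 11.84 in log2. Of the counts and correlations under an alternative, 219 stayed within 1.5 times or within their spread and 61 moved. Of the list calls, 1084 held, 231 were lost and 13 turned. Of the named genes, 2574 held, 295 lost the threshold, 50 gained it and 30 turned. Same-numbered arrays were not alike in their deviations from the group means (15 same-numbered pairs, r from -0.292 to 0.101, 1 over 0.1). The deviations of the control arrays mirror each other, and indicaxanthin array 3 weighs on those of its group. A shared effect of a trial is therefore not excluded. Per-array values from the authors' deposited tables were not run, since these hold none, and a fit of only the groups compared gives no separate value for the mean of the betalains. The cause of a change was not tested, except that fewer clusters are tested with the stricter filter and with protein-coding genes, and fewer arrays are used where arrays are left out.

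The counts of genes that moved, against control unless a pair is named, were as follows. The filter at the median gave 487 for indicaxanthin, 2210 for indoline-betacyanin and 971 for the mean. Only the groups compared gave 212 for indicaxanthin and 7308 for indoline-betacyanin, and 954 for indoline-betacyanin against indicaxanthin. Array weights gave 7459 for indoline-betacyanin, 8091 for the mean, 11307 between the betaxanthins and 5579 for indoline-betacyanin against indicaxanthin. Without indicaxanthin array 3 in any group the counts were 2127, 7173 and 8166 for indicaxanthin, indoline-betacyanin and the mean, 11178 between the betaxanthins and 5646 for indoline-betacyanin against indicaxanthin. Protein-coding genes alone gave 207 for indicaxanthin, 2126 for indoline-betacyanin and 695 for the mean. The plain t-test gave 3 for indicaxanthin (1 higher, 2 lower) and 314 for indoline-betacyanin against indicaxanthin. The trial number as a block gave 3658 for phenylalanine-betaxanthin. Leaving out 1 array gave 776 to 2127 for indicaxanthin, 1156 to 4914 for phenylalanine-betaxanthin, 1865 to 2623 for indoline-betacyanin, 1070 to 8166 for the mean, 0 to 11178 between the betaxanthins, 1678 to 5646 for indoline-betacyanin against indicaxanthin and 7277 to 7865 for indoline-betacyanin against phenylalanine-betaxanthin.

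List calls were lost for all 86 with an estimated correlation, where 0 lists shifted in every comparison, and for 55 with fry, where 1 shifted for indicaxanthin, 1 for the mean, 0 between the betaxanthins and 7 for indoline-betacyanin against indicaxanthin. For indicaxanthin 2 lists shifted with arrays centred and 2 with array weights. Leaving out 1 array gave 3 to 9 lists for indicaxanthin, 10 to 13 for phenylalanine-betaxanthin, 8 to 10 for indoline-betacyanin, 9 to 15 for the mean, 17 to 19 between the betaxanthins, and 11 to 13 and 14 to 16 for indoline-betacyanin against indicaxanthin and phenylalanine-betaxanthin. With 1 array left out, correlations of fold changes ranged from 0.324 to 0.949 (indicaxanthin and phenylalanine-betaxanthin), 0.437 to 0.606 (indicaxanthin and indoline-betacyanin) and 0.282 to 0.335 (the other pair), the first pairs at 0.324 and 0.606 without indicaxanthin array 3, and at 0.165 for the last with the block.

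Directions turned mostly with indicaxanthin array 3. With array weights and without that array, the median of indicaxanthin against control went to -0.25 and -0.403 for oocytes, and to 0.073 (test reversed) and -0.013 for the germ line. Leaving out any 1 array gave up to 2.54 and 1.676. For indoline-betacyanin against indicaxanthin it went to 0.09 and 0.109 for sperm and to 0.018 and 0.183 for oocytes, with single arrays left out giving as low as -1.19 and -2.843. Between the betaxanthins, ribosomal proteins turned to 0.023 after a further quantile normalization. Of genes not past the threshold with indicaxanthin, array weights turned daf-2 to -0.044, hsf-1 to -0.16, sod-3 to 0.15, gst-4 to 0.23, hsp-6 to -0.006, mtl-1 to 0.67, col-19 to -0.58, hsp-16.2 to -0.27 and daf-16 to 0.062. Without array 3 in any group daf-2 was -0.175. Leaving out 1 array gave daf-2 -0.184 to 0.3, hsf-1 -0.306 to 0.744, sod-3 -1.867 to 0.344, gst-4 -0.725 to 0.421, hsp-6 -0.095 to 0.291, mtl-1 -2.441 to 0.891, col-19 -0.848 to 2.571 and daf-16 -0.285 to 0.022. With indoline-betacyanin it gave col-19 -1.138 to 0.171. Centring turned daf-16 to 0.035 and, with indoline-betacyanin, hsp-6 to 0.025, and the block turned daf-2 to -0.015.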

Other observations

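Nothing in this part was tested as an explanation, and the genes named come from the rule for lists. With phenylalanine-betaxanthin, antioxidant genes leaned down without a list call: of 29, 8 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.43; camera adjusted p = 0.0632). Among them were the catalases ctl-1 (-1.28, SE 0.25) and ctl-2 (-1.62, SE 0.32) and the thioredoxin trx-3 (-3.38, SE 0.81). Of 30 genes activated by DAF-16, 14 fell and 2 rose (15 and 4 adjusted over the list alone; median -1.12; camera adjusted p = 0.0632), with cyp-35B1 at -4.38 (SE 1.04) and lea-1, a gene linked to desiccation tolerance, at 2.07 (SE 0.44). Of 15 genes repressed by DAF-16, 7 rose and 2 fell, at a median of -0.06 but a mean of 1.31 (camera adjusted p = 0.388), since yolk genes are among them. Of 22 genes of phenylalanine, tyrosine and proline metabolism 4 rose and 6 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.538). Examples were the tyrosine decarboxylase tdc-1 (3.61, SE 0.93) and the proline synthesis gene pycr-1 (-2.74, SE 0.72). Histone genes went both ways, 7 up and 15 down of 41 (7 and 18 adjusted over the list alone; camera adjusted p = 0.0996), from his-74 (5.13, SE 1.25) to his-24 (-1.95, SE 0.47). Of 63 genes of autophagy and lysosome 7 rose and 14 fell (6 and 13 adjusted over the list alone; camera adjusted p = 0.198), with vha-7 at 2.88 (SE 0.68) and the cathepsin gene cpr-4 at -3.58 (SE 0.75). Genes of the embryo had 7 up and 10 down of 25 (camera adjusted p = 0.229), with sdz-19 at -3.10 (SE 0.26) and pes-1 at -1.77 (SE 0.21). The third control implied by the authors' deposited tables had mean levels of 4.61 or 4.58 (antioxidant) and 5.2 or 5.1 (activated by DAF-16). These were 5.43 and 5.39, and 6.26 and 6.27, on the controls, and 4.68 to 4.8 and 5.21 to 5.35 on the treated arrays. It had tdc-1 at 6.6 or 6.63 and pycr-1 at 4.97 or 4.98, beside 5.42 to 5.67 and 4.75 to 5.26 on the treated arrays.

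Lists not described above had these counts with phenylalanine-betaxanthin, higher and lower by limma, with camera adjusted p: endoplasmic reticulum stress 4 and 8 (0.849), the mitochondrial response 3 and 1 (0.0632), targets of SKN-1 2 and 9 (0.128), insulin signalling 6 and 5 (0.923), and conjugating enzymes 12 and 20 (0.146). Further counts were metal handling 4 and 3 (0.923), immune effectors 36 and 72 (0.207), ribosomal proteins 1 and 3 (0.0996) and the intestine 3 and 8 (0.128). With indoline-betacyanin, genes of the embryo had 2 up and 5 down of 25 (2 and 6 adjusted over the list alone; camera adjusted p = 0.143). The transcription factor gene med-2 stood at 2.14 (SE 0.31), sdz-19 at -2.84 (SE 0.26) and pes-1 at -1.95 (SE 0.21). Autophagy and lysosome had 3 up and 12 down of 63, also adjusted over the list alone (camera adjusted p = 0.0752), with the beclin gene bec-1 at 0.88 (SE 0.13) and the cathepsin gene cpr-5 at -2.45 (SE 0.39). Targets of SKN-1 had 3 and 4 (camera adjusted p = 0.514), insulin signalling 1 and 0 (0.761), the antioxidants 3 and 3 (0.963), amino acid metabolism 1 and 1 (0.768), and lipid metabolism 5 and 4 (0.692). The germ line had 0 and 1 (0.514), muscle 3 and 4 (0.514), and oxidative phosphorylation and the proteasome 0 in limma (0.12 and 0.761).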
